A study of Mus musculus with 5 samples.

How the data were processed

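The samples were 3T3-L1 adipocytes, a mouse fibroblast-derived line that is differentiated in culture into fat cells with a hormone cocktail. Mature cells were infected with an adenovirus that expressed either beta-galactosidase (LACZ-Ad, the control) or mouse PU.1 (PU.1-Ad) and were taken 72 hours later, on day 10. PPARg was immunoprecipitated from both kinds of cells and PU.1 from PU.1-Ad cells only, and the recovered DNA was sequenced (ChIP-seq). The labels list 5 samples, of which the 2 input samples were not analysed here. Each of the 3 immunoprecipitations had 1 peak list. Per the design text of the series, DNA of 3 immunoprecipitations was pooled per condition, 2 biological replicates were sequenced, and input DNA came from the first replicate only. How the replicates were combined into 1 list per group is not given in the sources used here.

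The deposited lists hold positions and no measured value: per the file contents the authors gave each peak a chromosome, a start and an end, and no score, height, tag count or p-value. The submitters' processing notes name Bowtie 0.12.8, HOMER 3.15 and the mouse build mm9, without roles or settings, so the peak threshold, the handling of duplicate reads and the use of the inputs are not given in the sources used here. Sequencing depth is also unknown, so a list that is shorter because its library was shallower or less enriched looks the same as one that is shorter because fewer sites were bound. All peaks of a list had 1 width, 155 bp in the LACZ-Ad PPARg list, 141 bp in the PU.1-Ad PPARg list and 160 bp in the PU.1 list. Positions were read as BED (start counted from 0) and are printed counted from 1.

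Peaks carried no score, and every analysis that had been planned on a score used the order of the lines in its place. In both PPARg lists the peak names hold a running number per chromosome that rose down the file. The Spearman correlation between number and line was at least 0.999 (LACZ-Ad) and 0.998 (PU.1-Ad) on each chromosome. Within a chromosome the lines thus follow the numbering. That this order is a ranking, also across chromosomes, was assumed, and what was ranked is not stated. The PU.1 list has no names, so its order could not be checked in this way. The order was used within a list only, as 10 or 100 bins of equal size.

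The gene table at hand is on GRCm38, not mm9. Of the peaks on chromosome 7, 437 lie beyond the last gene of that table, so its coordinates are not those of these lists. No coordinate was moved between builds. The 12 gene lists that had been fixed before the data were examined (adipocyte, oxidation, macrophage, inflammatory, lymphocyte, fibroblast, hepatocyte, neuron and housekeeping genes), the promoter shares and the motif searches were therefore not run, and regions are named by mm9 position. The rule for genes that the text names could not be applied. Its part on peaks was applied with listing order for score: the 5 first-listed retained, lost, gained and PU.1 peaks.

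A LACZ-Ad PPARg peak was called retained when a PU.1-Ad PPARg peak overlapped it by at least 1 bp and lost when none did. A PU.1-Ad PPARg peak with no overlapping LACZ-Ad PPARg peak was called gained. These words refer to membership in the lists. Overlaps were computed from peak centres with numpy 2.4.6 and pandas 2.3.3 and checked against bedtools 2.31.1. Shares have exact Clopper-Pearson 95% intervals (scipy 1.17.1), which cover counting error only. Overlap by chance was taken from 1000 circular shifts of the second list within each chromosome and from 1000 shifts of 20 to 200 kb, which keep the regional density of peaks. Odds ratios were tested with Fisher's exact test (two-sided), stratified over listing bins by Mantel-Haenszel (statsmodels 0.14.6), and given a second interval from 1000 bootstrap draws of 10 Mb blocks, since neighbouring peaks are not independent. With 1 list per group, every interval and p-value describes these lists and not the spread between cultures. The procedure was tested on simulated data made from the 42485 LACZ-Ad PPARg positions: true odds ratios of 0.4, 1 and 2.5 were recovered as 0.4, 1.04 and 2.52. Alternatives covered the overlap rule, the autosomes alone, the placement of shifted peaks, shortened lists, stratification by listing order and the removal of the windows of the first-listed lost peaks (77 to 78 Mb of chromosome 2 and 117 to 118 Mb of chromosome 10) and of the first Mb with peaks of each chromosome.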

Results

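PPARg, the nuclear receptor that drives adipocyte differentiation, and PU.1, the ETS-family factor that directs macrophage and B cell development, were mapped by ChIP-seq in 3T3-L1 adipocytes. The cells carried either a control adenovirus expressing beta-galactosidase (LACZ-Ad) or one expressing PU.1 (PU.1-Ad). There was 1 peak list per immunoprecipitation: 42485 PPARg peaks in LACZ-Ad cells, 8785 PPARg peaks in PU.1-Ad cells and 40922 PU.1 peaks in PU.1-Ad cells. The lists covered 6.58, 1.24 and 6.55 Mb, and each held peaks on 20 chromosomes. The median distance between neighbouring peaks was 14.0 kb, 60.4 kb and 17.3 kb, in the same order. The lists give no tag counts, so the depth behind a peak is unknown, and no list has a replicate.

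The first comparison asked how the PPARg cistrome of adipocytes differed once PU.1 was expressed. PPARg was called at far fewer sites in PU.1-Ad cells, with 0.207 times as many peaks as in LACZ-Ad cells. Of the LACZ-Ad PPARg peaks, 8367 were retained, which is 19.7% (exact 95% interval 19.3 to 20.1), and 34118 were lost. Nearly the whole PU.1-Ad list lay inside the LACZ-Ad list: 95.2% of its peaks (94.8 to 95.7) overlapped a LACZ-Ad peak, and 418 peaks, or 4.76% (4.32 to 5.22), were gained. The PPARg sites of PU.1-Ad cells were mostly a subset of the control sites. PU.1-Ad PPARg peaks shifted along their chromosome overlapped 0.108% of LACZ-Ad peaks on average and 0.167% at most in 1000 shifts (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The centres of retained peaks lay a median of 12 bp apart in the 2 lists. Without tag counts the drop in peak number cannot be separated from a difference in depth or enrichment between the 2 libraries.

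Retention followed the order in which the LACZ-Ad list gives its peaks. In the first-listed decile 94.3% of peaks were retained (93.6 to 95.03), in the second 57.8% (56.3 to 59.3), in the third 23.6% (22.3 to 24.9) and in the last 0.706% (0.477 to 1.01). Among as many first-listed LACZ-Ad peaks as the PU.1-Ad list holds, 74.7% were retained (73.8 to 75.6). The 5 first-listed retained peaks lay at chromosome 10 position 117154752 to 117154906, chromosome 2 position 77831105 to 77831259, chromosome 5 position 64717758 to 64717912, chromosome 7 position 26177045 to 26177199 and chromosome 5 position 124676668 to 124676822 (mm9). The centre of the PU.1-Ad PPARg peak was 3 to 19 bp from the LACZ-Ad centre at these sites. Losses near the top of the list were few: 13 of the first 1000 peaks were lost. Of these, 6 lay in the window from 77 to 78 Mb of chromosome 2 and 2 in the window from 117 to 118 Mb of chromosome 10. A further 3 lay in the first Mb with peaks of a chromosome. Both windows were chosen because they held the first-listed lost peak of their chromosome, so these counts are no test of clustering. The first-listed retained peaks of chromosomes 10 and 2 lay in the same windows. The 5 first-listed lost peaks were chromosome 10 position 117181155 to 117181309, chromosome 10 position 117174214 to 117174368, chromosome 2 position 77744039 to 77744193, chromosome 11 position 3061265 to 3061419 and chromosome 2 position 77789585 to 77789739.

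All 20 chromosomes had lower peak numbers in the PU.1-Ad PPARg list than in the LACZ-Ad list. The retained share ranged over the autosomes from 16.0% on chromosome 18 (220 of 1373 peaks; 14.1 to 18.1) to 24.1% on chromosome 6 (703 of 2913 peaks; 22.6 to 25.7) and was 11.7% on the X chromosome (83 of 709 peaks; 9.43 to 14.3). The listing order of their peaks alone predicted 16.4%, 27.1% and 10.6% for these chromosomes. The densest 1 Mb window of the LACZ-Ad list, chromosome 2 from 167000001 to 168000000, held 87 PPARg peaks in LACZ-Ad cells, of which 19 were retained. It also held 4 gained PPARg peaks and 73 PU.1 peaks.

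**Figure D1:**
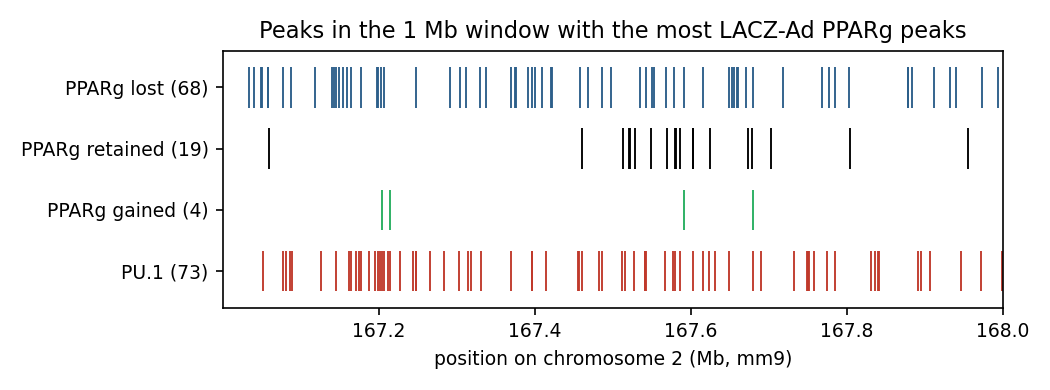
Positions of peaks on chromosome 2 from 167 to 168 Mb (mm9; x axis in Mb), the 1 Mb window with the most LACZ-Ad PPARg peaks, chosen after the peaks had been counted; each vertical line is 1 peak and the number in each row label is its count. Of the 87 LACZ-Ad PPARg peaks, 19 were retained, and 73 PU.1 peaks were called in the same window.

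The second comparison asked whether PU.1 bound where PPARg was lost. It was found less often there than where PPARg stayed. PU.1 peaks overlapped 8.54% of lost PPARg peaks (2915 of 34118; 8.25 to 8.85) and 17.6% of retained ones (1471 of 8367; 16.8 to 18.4). The odds ratio of a PU.1 peak at lost against retained peaks was 0.438 (exact 95% interval 0.409 to 0.469; Fisher's exact test, two-sided, p = 2.58e-116; 0.408 to 0.467 over 274 blocks of 10 Mb). Counted the other way, 33.5% of LACZ-Ad PPARg peaks with a PU.1 peak were retained (32.1 to 34.96), against 18.1% of those without (17.7 to 18.5). Of all LACZ-Ad PPARg peaks, 10.3% had a PU.1 peak (10.0 to 10.6), so 89.7% of the control PPARg sites, and 31203 of the 34118 lost ones, had none. These overlaps exceeded chance in both classes: PU.1 peaks shifted by 20 to 200 kb overlapped 1.01% of lost and 1.12% of retained peaks on average, and at most 1.19% and 1.49% (one-sided permutation p = 0.001 for each, the smallest that 1000 shifts can give).

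The odds ratio of retention with against without a PU.1 peak was farthest from 1 among the late-listed PPARg sites, while the retained shares themselves lay farthest apart in the third decile, at 42.9% with (38.6 to 47.3) and 20.9% without (19.6 to 22.2). In the first-listed decile 96.1% of peaks with a PU.1 peak (94.2 to 97.6) and 94.1% of those without (93.3 to 94.8) were retained, with an odds ratio of retention of 1.57 (0.997 to 2.57; Fisher's exact test, Benjamini-Hochberg adjusted over the 10 deciles, p = 0.0506). In the fifth decile the shares were 15.0% (11.9 to 18.6) and 3.85% (3.26 to 4.51). In the last decile 21 of 258 peaks with a PU.1 peak were retained, or 8.14% (5.11 to 12.2), against 9 of 3990 without, or 0.226% (0.103 to 0.428), an odds ratio of 39.1 (16.9 to 98.0; Fisher's exact test, adjusted p = 2.81e-19). PU.1-Ad PPARg peaks shifted by 20 to 200 kb overlapped 0.25% of all LACZ-Ad peaks on average and 0.33% at most. The last-decile share without a PU.1 peak was close to this value, which is not its chance level. Shifted peaks could land at any site, whereas most PU.1-Ad peaks lay at LACZ-Ad sites listed early. Whether that share exceeded chance was not tested, and the odds ratio there rests on the 9 retained peaks without a PU.1 peak. The odds ratio was above 1 in each of the 10 deciles and its adjusted p was under 0.05 in every decile but the first. A logistic model gave a 1.44-fold rise in the odds ratio per decile (log odds 0.36, SE 0.026). Its size depends in part on the late deciles, where few peaks without a PU.1 peak were retained. Over the 10 deciles the stratified odds ratio of a PU.1 peak at lost against retained peaks was 0.334 (0.301 to 0.370).

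**Figure D2:**
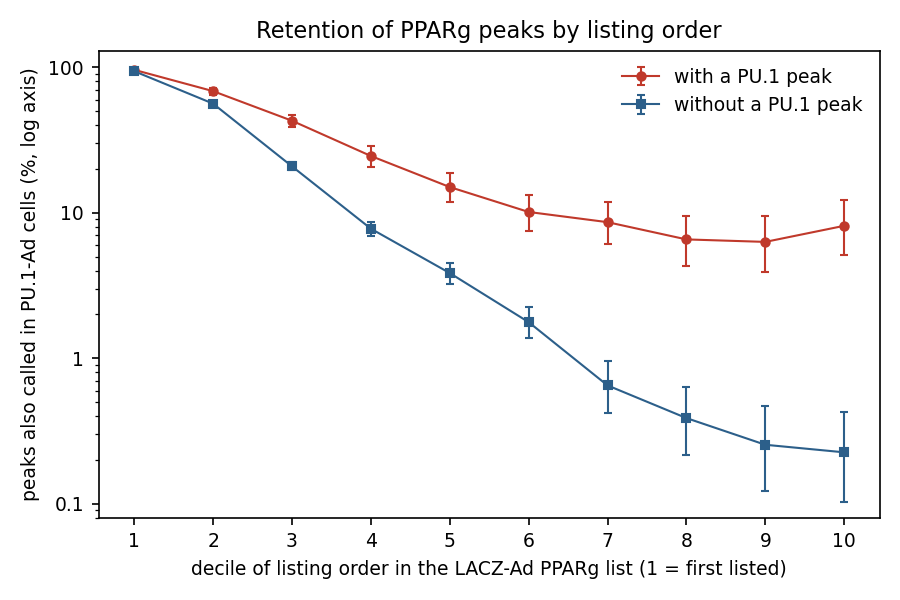
Share of LACZ-Ad PPARg peaks also called in PU.1-Ad cells (y axis, %, log scale) by decile of their order in the list (x axis, 1 is first listed), for peaks with (circles) and without (squares) an overlapping PU.1 peak; bars are exact 95% intervals. They start at 96.1% and 94.1% in decile 1 and part to 8.14% with and 0.226% without a PU.1 peak in decile 10.

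The third comparison concerned the PPARg peaks present in PU.1-Ad cells only. Most of them coincided with PU.1: 275 of the 418 gained peaks, or 65.8% (61.0 to 70.3), had a PU.1 peak, against 17.4% (1454 of 8367; 16.6 to 18.2) of retained peaks as placed in PU.1-Ad cells. The odds ratio was 9.14 (7.38 to 11.4; Fisher's exact test, two-sided, p = 1.91e-99; 7.53 to 11.3 over 266 blocks) and 11.2 (8.98 to 13.9) over listing deciles of the PU.1-Ad list. Shifting PU.1 peaks by 20 to 200 kb left 1.12% of gained peaks with a PU.1 peak on average and 3.11% at most. Among the peaks with an overlapping PU.1 peak, PPARg centres of the PU.1-Ad list lay a median of 23.5 bp from the PU.1 centre at the 275 gained and 37.5 bp at the 1454 retained peaks. Centres of the LACZ-Ad list lay a median of 45.5 bp away at the 1471 retained and 49.5 bp at the 2915 lost peaks. The 5 first-listed gained peaks were chromosome 2 position 77831499 to 77831639, chromosome 4 position 3017393 to 3017533, chromosome 18 position 56099091 to 56099231, chromosome 8 position 74092273 to 74092413 and chromosome 17 position 14916324 to 14916464. A PU.1 centre lay within 71 bp of all but the one on chromosome 4, whose nearest PU.1 centre was 381101 bp away. Those on chromosomes 2, 8 and 17 also lay beside a control site, with a LACZ-Ad PPARg centre 387, 324 and 203 bp away. For those on chromosomes 4 and 18 it was 549657 and 29049 bp away. Of the gained peaks, 115 had a LACZ-Ad PPARg centre within 500 bp that did not overlap them, so 27.5% (23.3 to 32.1) lay beside a control site.

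**Figure D3:**
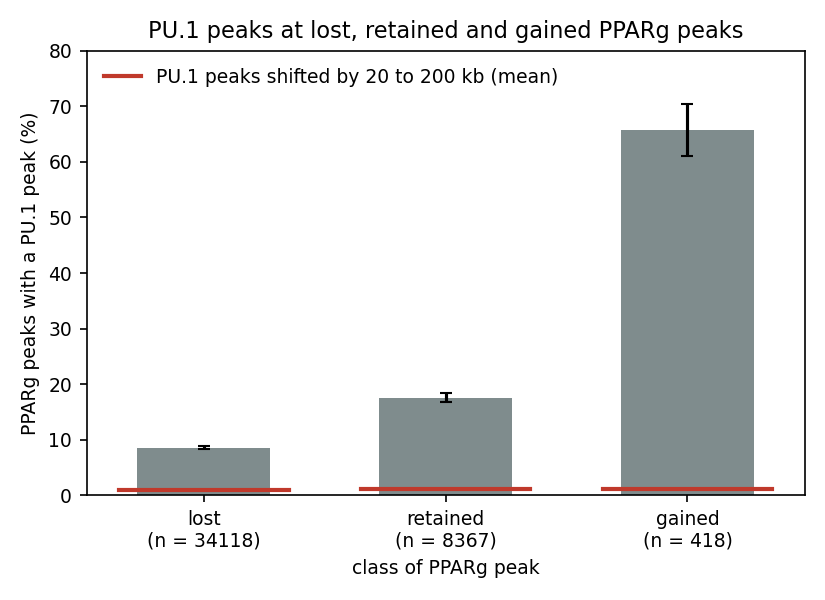
Share of PPARg peaks with an overlapping PU.1 peak (y axis, %) for lost, retained and gained peaks; bars start at 0, error bars are exact 95% intervals, and the lines mark the mean over 1000 shifts of the PU.1 peaks by 20 to 200 kb. The share is 8.54% at lost, 17.6% at retained and 65.8% at gained peaks, and about 1% for shifted PU.1 peaks.

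Counted cumulatively, overlapping peaks included, within 1 kb of a PU.1 centre lay 18.0% of lost (17.6 to 18.4), 29.7% of retained (28.7 to 30.7) and 74.4% of gained PPARg peaks (69.9 to 78.5). Within 10 kb the shares were 54.2% (53.7 to 54.7), 66.5% (65.4 to 67.5) and 88.3% (84.8 to 91.2), and within 50 kb they were 88.8%, 93.8% and 97.1%. Among LACZ-Ad PPARg peaks without an overlapping PU.1 peak, 20.8% of those with a PU.1 centre within 10 kb were retained, against 15.2% of the others. This difference was not seen at equal listing, where the odds ratio of retention was 1.005 (0.923 to 1.09) over 100 listing bins.

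**Figure D4:**
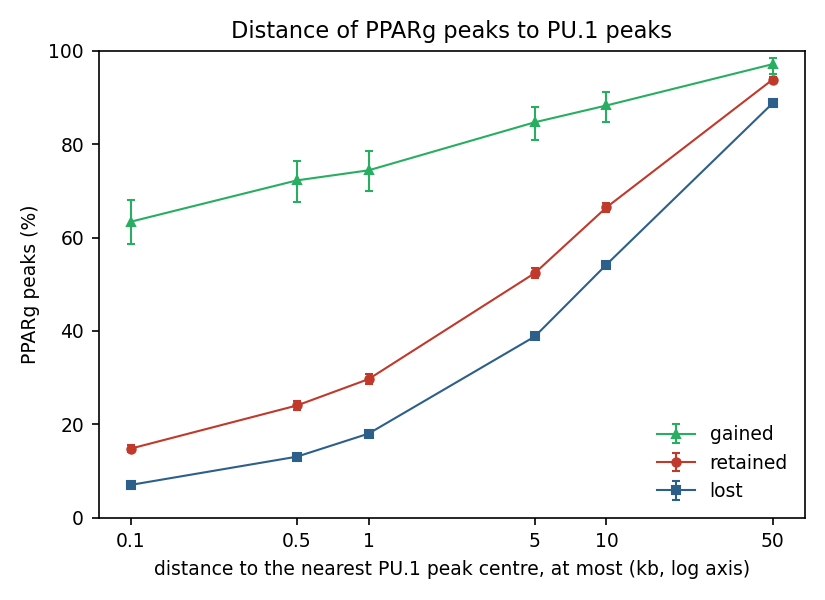
Cumulative share of PPARg peaks (y axis, %) with a PU.1 peak centre at most a given distance away (x axis, kb, log scale), for lost (squares), retained (circles) and gained (triangles) peaks, peaks with an overlapping PU.1 peak included; bars are exact 95% intervals. Gained peaks lie above retained and retained above lost peaks at every distance, from 63.4%, 14.8% and 7.05% at 0.1 kb to 97.1%, 93.8% and 88.8% at 50 kb.

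Seen from PU.1, the expressed factor bound mainly outside the PPARg sites. Of the 40922 PU.1 peaks, 88.6% (88.3 to 88.9) overlapped no PPARg peak of either list. A LACZ-Ad PPARg peak was present at 10.7% (10.4 to 11.02) and a PU.1-Ad PPARg peak at 4.23% (4.03 to 4.42). Of PU.1 peaks at a LACZ-Ad PPARg site, 32.7% (31.3 to 34.1) also had a PPARg peak in PU.1-Ad cells, against 0.807% (0.718 to 0.905) of PU.1 peaks elsewhere, or 295 of 36536. Overlap with PPARg was more frequent among first-listed PU.1 peaks: 15.0% of the first decile (13.9 to 16.1) and 7.16% of the last (6.39 to 7.99) had a LACZ-Ad PPARg peak, and 8.53% (7.69 to 9.42) and 2.42% (1.97 to 2.94) had a PU.1-Ad one. The 5 first-listed PU.1 peaks all lay on chromosome 10, at positions 118059270 to 118059429, 116855061 to 116855220, 117154848 to 117155007, 116934011 to 116934170 and 117213079 to 117213238. The third of these overlapped the first-listed PPARg peak of both PPARg lists.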

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

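The cell cultures had no replicate lists, so no library could be left out, and no paired analysis was possible because each group has 1 list. Every alternative based on listing order and the removal of the windows of the first-listed lost peaks (77 to 78 Mb of chromosome 2 and 117 to 118 Mb of chromosome 10) and of the first Mb with peaks of each chromosome was chosen after the data had been seen. Of 41 alternative values, 30 stayed (the same side of the threshold for an odds ratio, within the 95% interval for a share, within 1.5 times for a ratio or fold) and 11 moved. Both odds ratios kept their direction and significance in every alternative run, between 0.328 and 0.606 for lost against retained peaks and between 8.32 and 12.9 for gained against retained peaks. Requiring an overlap of 50% of the shorter peak gave 5.28% gained peaks and 7.61% of LACZ-Ad PPARg peaks with a PU.1 peak, with a fold of PU.1 overlap over shifted positions of 27.9 instead of 19.4. Accepting centres within 500 bp gave 20.3% retained, 3.45% gained and 15.3% with a PU.1 peak, and that fold was then 9.15. It was 10.0 with shifts of 20 to 200 kb, since PPARg and PU.1 peaks share dense regions. With the LACZ-Ad list limited to as many first-listed peaks as the PU.1-Ad list, 74.7% were retained instead of 19.7%. Most of these peaks were thus retained and not lost, so the retained share depends on how far down the control list is read. With each list limited to its first-listed 50%, 3.46% were gained and 7.66% of LACZ-Ad PPARg peaks had a PU.1 peak, and with only the PU.1 list shortened so 6.26% did. Stricter thresholds on a peak score, stratification by score, gene windows, promoter width and motif windows were not run, for lack of a score and of mm9 genes and sequence. Depth, which is unknown, limits the peak number of each list and with it every count of lost sites.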

Other observations

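The tests of regional density, of shared fate of neighbours and of PU.1 listing order were set before their results were seen, and the odds ratio of a PU.1 peak at lost against retained peaks was planned before the data were examined. Its use as a test of displacement, and the remaining tests, were chosen after. Of the first 20 PU.1 peaks, 12 lay on chromosome 10 between 116000001 and 119000000, a region with 0.156% of all PU.1 peaks, and 3 of the first 20 LACZ-Ad and 1 of the first 20 PU.1-Ad PPARg peaks lay there too. Among the 552 windows of 1 Mb with at least 30 LACZ-Ad PPARg peaks, retention was lowest at 3.03% (1 of 33 peaks) on chromosome 11 from 20000001 to 21000000 and on chromosome 13 from 63000001 to 64000000, where listing order predicted 5.29% and 10.5%. It was highest at 46.7% (14 of 30 peaks) on chromosome 3 from 10000001 to 11000000, where listing order predicted 41.7%.

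Most control PPARg peaks were missing from the PU.1-Ad list. Displacement by PU.1 bound at the same site, as the main cause, is argued against by the 31203 of 34118 lost peaks without a called PU.1 peak. This holds as far as the PU.1 list is complete. Its threshold and depth are unknown too, and PU.1 bound below the threshold would be missed. Counted by distance, 18.0% of lost peaks lay within 1 kb of a PU.1 centre. The odds ratio of a PU.1 peak at lost against retained peaks was 0.438 and not above 1. It cannot decide on displacement at PU.1 sites, because PU.1-bound DNA in the PPARg immunoprecipitate, left open below, would also lower it. A less sensitive PU.1-Ad PPARg library could account for the loss in listing order, with 94.3% of the first-listed decile retained. Lower PPARg occupancy across sites in PU.1-Ad cells predicts the same order, with 0.706% of the last-listed decile retained, and cannot be told apart from sensitivity without tag counts and inputs.

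Retained peaks had a PU.1 peak more often than lost ones. Early listing is argued against, since over 100 listing bins the odds ratio of a PU.1 peak at lost against retained peaks was 0.328 (0.295 to 0.364). A loss that depended on sensitivity alone cannot be judged from this value. What the listing order reflects is not stated, so sites within a bin may still differ in how readily they are called. PU.1 within 10 kb, taken as 1 class, is argued against as well. Among peaks with no overlapping PU.1 peak, one within 10 kb went with an odds ratio of retention of 1.005 (0.923 to 1.09) at equal listing, although the raw shares were 20.8% and 15.2%. Shorter distances were not tested at equal listing, so an effect of PU.1 close to the site is not excluded. A small amount of PU.1-bound DNA in the PPARg immunoprecipitate that lifts weak sites over the threshold stays open, as does PPARg binding that is kept where PU.1 binds. Retention at first-listed against last-listed PU.1 peaks, which both predict to be higher, had an odds ratio of 1.21 (0.986 to 1.48) in deciles 3 to 10 and cannot decide between them. The prediction also takes the order of the PU.1 list as a ranking of PU.1 signal, which could not be checked.

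Most gained PPARg peaks had a PU.1 peak. Regional density is argued against, because PU.1 peaks moved by 20 to 200 kb overlapped at most 3.11% of gained peaks. PU.1-bound DNA carried into the PPARg immunoprecipitate stays open: of the first 1000 PU.1 peaks without a LACZ-Ad PPARg peak, 47 had a PU.1-Ad PPARg peak, or 4.7% (3.47 to 6.20), against 0.807% of all such PU.1 peaks. The share was far below the majority that had been set as the mark of carry-over. It was also above that of all such PU.1 peaks, so neither outcome set for this test was reached. The test likewise takes the unchecked order of the PU.1 list as a ranking. A moved peak centre beside a control site could account for at most the 27.5% (23.3 to 32.1) of gained peaks within 500 bp of one. PU.1-dependent PPARg binding at these sites also remains open, as a hypothesis.

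Peak centres offered a further test of PU.1-dependent signal. Where 1 PU.1 peak overlapped a retained site in both lists, the PPARg centre in PU.1-Ad cells was nearer to the PU.1 centre than the LACZ-Ad centre in 59.7% of 1403 sites (57.0 to 62.2; exact binomial test, two-sided, p = 4.81e-13), with medians of 36.5 and 44.5 bp. In the last-listed 50% of the LACZ-Ad list this was 66.0% of 147 sites (57.7 to 73.6). Where the PU.1 peak lay within 1 kb and overlapped neither centre it was 50.2% of 960 sites (47.0 to 53.4; exact binomial test, p = 0.923). The medians there were 472.5 bp (LACZ-Ad) and 473.5 bp (PU.1-Ad). At such distances a difference in how precisely the lists place centres would not show, so this comparison cannot exclude it. The shift may mean that part of the PPARg signal at shared sites lay at the PU.1 position, from either kind of signal named above. Whether centre precision alone would give it was not tested.

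Neighbouring PPARg peaks shared their fate to a small degree. Over 17685 pairs of peaks at most 10 kb apart, the correlation across peaks of their deviations from the retained share at equal listing was 0.038, above the highest of 1000 permutations within listing bins (0.024; one-sided permutation p = 0.001, the smallest they can give). In the 13966 pairs in which neither peak had a PU.1 peak it was 0.036. Peaks are not independent replicates, and the correlation concerns only what listing order leaves unaccounted for.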
